A study of Homo sapiens with 192 samples.

How the data were processed

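Surface proteins of single Jurkat and Raji cells were measured by proximity sequencing (Prox-seq). Jurkat is a human T cell leukaemia line and Raji a human B cell line from a Burkitt lymphoma. In this assay cells are stained with antibodies that carry DNA oligonucleotides, and a pair of oligonucleotides bound close together is ligated into a proximity ligation (PLA) product that names 2 targets. Per the labels, both lines were grown in the same serum-supplemented medium without treatment, PLA products were extracted from single cells in a plate-based workflow, and the library was made from them by PCR. The labels give 96 wells for each line, 192 samples in all, and each sample is 1 cell.

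The deposited table holds whole-number counts of 100 ordered PLA products in the 192 wells, which are all ordered pairs of 10 targets. The counts carry no normalization, as seen from whole numbers with different totals per well. How reads were matched to antibody barcodes, how errors in barcodes were handled and whether molecular identifiers were collapsed is not given in the sources used here. Each column was matched to its sample by its title, and 0 columns stayed unmatched. No pair of wells with counts held identical columns. The deposited list of antibody barcodes was not used. The first target of a product name is called the first position and the other the second position, since the sources used here do not state which probe set each belongs to. They also do not describe the targets named Biotin and free_oligo.

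The labels name no separate cultures, so each line was treated as 1 culture and cells were not treated as replicates. No test between the lines was made and no p-value is given. The wells of each line carry a full set of plate positions of their own under the same plate name, so a difference between plates and a difference between lines cannot be told apart. Counts were summed over the wells of a line. Sums carry exact Poisson intervals, shares exact Clopper-Pearson binomial intervals, and ratios of shares exact conditional binomial intervals, all at 95%. These intervals, and the limit of 3 counts that a count of 0 allows, cover counting error only. They leave out the spread between cells and cultures and any repeated counting of 1 molecule by PCR. An interval for a number of wells treats the wells of a line as independent draws. It thus describes cells of 1 culture and leaves out the spread between cultures. SDs and quantiles over wells describe the wells and are not errors of a line.

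A product added 1 probe end to each of its targets, and the share of a target is its part of all probe ends of the line. Products were compared between the lines by the ratio of their shares of all counts. Products with a share of at least 0.1% in a line and a ratio of at least 2 were counted as higher there. A product with no count in the other line was set against 3 counts summed over that line. Within each line, the count expected under random ligation was, for each well, the first-position total of 1 target times the second-position total of the other, divided by the well's total, and was then summed over wells. Observed over expected was ranked for products with at least 100 counts, and those at or above 1.5 were counted.

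Before the data were examined, these measures, their thresholds and the target lists were fixed. The T cell list matched CD3, CD28 and PD1 in the panel, the B cell list matched B7, HLADR and PDL1, and the list of broadly expressed adhesion and surface proteins matched ICAM1 and CD147. The background control was free_oligo. Biotin belonged to no list, and no marker of another cell type was among the 10 targets. The text names all targets. It names the 10 products with the highest share ratio in each direction among those of at least 0.1% in the higher line. The 10 with the highest observed over expected in each line are also named. So are all homotypic products, which pair a target with itself, and pairs from a list of known or possible partners. Symbols were looked up by name or synonym in a RefSeq table of assembly GRCh38.p14. CD28, ICAM1, B7 (CD80), PDL1 (CD274) and CD147 (BSG) had a single match, which for B7 does not settle whether the antibody binds CD80 or CD86. PD1 matched several genes through synonyms, and CD3, HLADR, Biotin and free_oligo had none.

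The measures were tested on simulated data. In 100 draws per line, with each well's products redrawn from its own totals under random ligation, observed over expected of products with at least 100 counts in the draw lay between 0.812 and 1.30 in Jurkat and between 0.808 and 1.31 in Raji, and 0 products reached 1.5. This leaves out products whose count fell below 100 in the draws, so the range of each product with at least 100 real counts was added after the data were seen. Over these products the extremes were 0.531 and 1.57 in Jurkat, where free_oligo:Biotin reached 1.5 in 1 draw, and 0.575 and 1.48 in Raji, where 0 products did. When 5 products of Raji were raised 4 times, all 5 were counted by the share ratio with 0 others, and when 5 were raised 1.5 times, 0 were. Observed over expected has a ceiling for abundant targets, because their homotypic product is a large part of their own totals. A homotypic product set to 2 times random ligation gave a mean observed over expected of 1.65 for CD28 and 1.63 for CD3, but 1.09 for PD1 and 1.20 for CD147 in Jurkat. In Raji it gave 1.29 for HLADR, 1.17 for PDL1, 1.14 for ICAM1 and 1.67 for CD147. For that reason an odds ratio was added after the data were seen. It sets the 2 homotypic products of a pair of targets against their 2 mixed products, is pooled over wells by the Mantel-Haenszel formula, and is near 1 under random ligation.

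Wells with at least 1 count were kept, and 1 Raji well without counts was left out. The alternatives were wells within 3 median absolute deviations of the median log10 total, the upper or lower rows of the plate, leaving out the control, the mean over wells in place of the sum, counts per well, other minimum shares and counts, both orientations of a pair summed, 2 other ways to obtain the expected count, a median over wells, and thinning of each well to 2411 counts. Alternatives without free_oligo and Biotin, without wells under 1000 counts (for target shares also as a mean over wells), without Raji wells A01 and B01 and with odds ratios of the summed counts were chosen after the data were seen. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9.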

Results

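The series counted ligation products between 10 targets on single cells of a T cell line, Jurkat, and a B cell line, Raji. It was made for work on the prediction of protein interactions from proximity sequencing. Jurkat filled 96 wells, all with counts, and held 623875 counts (95% Poisson interval 622328 to 625425). The median per well was 6143 (interquartile range 3058.5 to 8576.2), and totals ran from 7 to 20199, with the second lowest at 731. Of the 96 Raji wells, 1 held no counts. The other 95 held 1227612 counts (1225441 to 1229786), with a median of 12549 (7886.5 to 17080) and a range from 3264 to 33603. Raji wells were thus deeper on average, with 12922 counts per well against 6499 in Jurkat, and the lines were compared by shares. Each line was treated as 1 culture, since the labels name no separate ones, so the differences between the lines have no replicate check.

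The first comparison asked which surface targets distinguish the lines. All 3 targets of the T cell list had a higher share of probe ends in Jurkat. PD1, an inhibitory receptor of activated T cells, made up 50.6% of Jurkat probe ends (95% interval 50.5 to 50.7) and 0.0165% of Raji probe ends (0.0149 to 0.0182), a ratio of 3069 (2784 to 3391). CD3, the signalling part of the T cell receptor complex, made up 7.01% against 0.00798%, a ratio of 878 (763.5 to 1016). CD28, a costimulatory receptor of T cells, made up 4.77% against 0.0137%, a ratio of 349 (313 to 389). The list as a whole held 62.4% of Jurkat probe ends (62.3 to 62.5) and 0.0382% of Raji probe ends (0.0358 to 0.0407).

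All 3 targets of the B cell list had a higher share in Raji. HLADR, a class II molecule that presents peptides to T cells, made up 23.4% of Raji probe ends and 0.0253% of Jurkat probe ends, which was 925 times higher in Raji (828 to 1036). This ratio is -9.85 as a log2 of Jurkat over Raji. By the mean of the shares within wells it was -6.19, where the Jurkat well with 7 counts had an HLADR share of 28.6%, and without wells under 1000 counts that mean gave -9.41. PDL1, the ligand of PD1, made up 29.01% against 0.122% and was 237.8 times higher (226 to 250.2). B7, a costimulatory ligand of CD28, was rare in both lines, with 0.411% against 0.0127%, and was 32.2 times higher in Raji (27.6 to 37.9). The list held 52.8% of Raji probe ends (52.8 to 52.9) and 0.160% of Jurkat probe ends (0.153 to 0.167).

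The broadly expressed targets divided between the lines. ICAM1, an adhesion molecule that binds leukocyte integrins, was the most frequent target of Raji at 39.03% (38.97 to 39.09), against 1.37% in Jurkat, a ratio of 28.5 in favour of Raji (28.09 to 28.95). CD147, a glycoprotein found on most cell types, made up 34.7% of Jurkat probe ends and 7.40% of Raji probe ends and was 4.70 times higher in Jurkat (4.67 to 4.72). Together the 2 targets held 36.1% of Jurkat and 46.4% of Raji probe ends. Since a share depends on the other targets of the line, counts per well were also set side by side, and the mean count of CD147 probe ends was 4514 per Jurkat well and 1912 per Raji well. The background control free_oligo had a share of 1.11% in Jurkat and 0.532% in Raji, a ratio of 2.08 (2.03 to 2.13), but a similar number of probe ends per well, 143.99 and 137.55. Biotin made up 0.227% and 0.166%. Its share was 1.37 times higher in Jurkat (1.30 to 1.44), whereas its mean number of probe ends per well was lower there, 29.5 against 42.8.

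**Figure D1:**
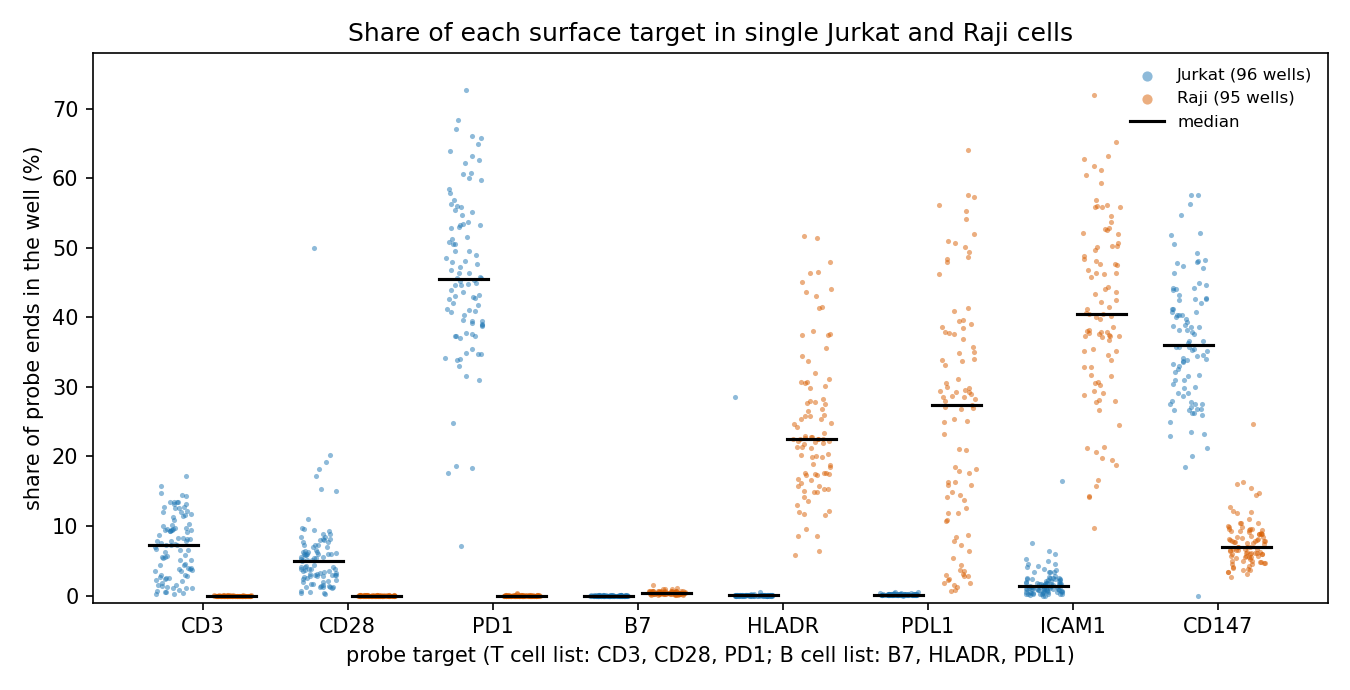
Share of each target among the probe ends of a well, in percent, for 96 Jurkat and 95 Raji wells; each point is 1 cell and the black bar is the median over wells. PD1 and CD147 lead in Jurkat with medians of 45.5% and 36.1%, ICAM1, PDL1 and HLADR lead in Raji with medians of 40.4%, 27.5% and 22.5%, and PDL1 spreads from 0.612% to 64.1% over Raji wells. The isolated Jurkat points for CD28 at 50% and HLADR at 28.6% belong to the well with 7 counts.

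Single cells followed the same division. Probe ends of the T cell list outnumbered those of the B cell list in 96 of 96 Jurkat wells (95% Clopper-Pearson interval 96.2 to 100%). In Raji they did so in 0 of 95 wells (0 to 3.81%). Among the probe ends of both lists, the T cell list held 97.85% or more in each Jurkat well except the well with 7 counts, where it held 71.4%, and at most 1.12% in any Raji well. Within a line, targets differed in how much they varied. The PD1 share averaged 46.1% ± 11.7 (SD over 96 wells) in Jurkat, and CD3 averaged 7.14% ± 4.41. In Raji, ICAM1 averaged 40.70% ± 13.03 and HLADR 24.5% ± 10.4 (SD over 95 wells). PDL1 averaged 25.8% ± 16.7, the widest SD of the 10 targets in that line.

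The next comparison concerned pairs of targets. Of the 27 products with a share of at least 0.1% in Jurkat, 25 were at least 2 times higher there, and 21 of these held a target of the T cell list. Of the 25 such products in Raji, 24 were at least 2 times higher there, and 19 held a target of the B cell list. The most frequent Jurkat product was PD1:PD1, with 158982 counts or 25.5% of the line, against 45 counts in Raji, a ratio of 6952 (5195 to 9531). Of those 45 counts, 26 lay in Raji well B01, and without that well the ratio was 16361 (10477 to 27176). The other 6 products named here with at least 10 counts in the lower line moved by less than 1.5 times when single wells of that line were left out. Products of PD1 with CD147 came next, with 112588 counts of CD147:PD1 against 12 in Raji, a ratio of 18462 (10569 to 35730). PD1:CD147 had 105715 counts against 10, a ratio of 20802 (11311 to 43380).

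Products of CD3 and CD28 were nearly absent from Raji, so their ratios had wide intervals. PD1:CD3 reached 26140 counts against 1, a ratio of 51436 (9231 to 2031699), and CD3:PD1 reached 22774 against 2, a ratio of 22406 (6202 to 185028). CD147:CD3 reached 11524 counts and CD147:CD28 8346, each against 1. PD1:CD28 and CD28:PD1 reached 14512 and 13969 counts, each against 4. CD3:CD3 had 6214 counts in Jurkat and 0 in Raji. Set against 3 counts, or 0.000244% of Raji, its ratio was 4076, with a lower 95% bound of 3314.

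In Raji the leading products joined ICAM1, PDL1 and HLADR. ICAM1:ICAM1 had 212094 counts or 17.3% of the line, against 0.0212% of Jurkat counts, a ratio of 817 (689 to 976). PDL1:PDL1 had 138791 counts against 5, a ratio of 14107 (6045 to 43447), and HLADR:HLADR had 81223 against 14, a ratio of 2948 (1757 to 5393). ICAM1 in the first position with PDL1 and with HLADR gave 145543 and 137454 counts, against 11 and 6 in Jurkat. With ICAM1 in the second position, PDL1:ICAM1 gave 85854 counts against 7, and HLADR:ICAM1 80867 against 1, a ratio of 41097 (7376 to 1623256). PDL1:HLADR had 72396 counts against 2, and HLADR:PDL1 had 73779 against 0, at least 12498-fold higher in Raji. CD147:HLADR was 844 times higher (493 to 1585).

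These ratios depend on the abundance of the targets and can also depend on how they pair. PD1:PD1, for example, had 45 counts in Raji where random ligation would give 0.177. Of these counts, 34 lay in wells A01 and B01, and the product exceeded its expected count in 12 of 95 wells. The origin of these counts was not settled, so they do not show that PD1 pairs with itself on Raji cells. Each line was therefore also examined for products above what random ligation of its own probe ends gives. In Jurkat, 3 of 43 products with at least 100 counts reached 1.5 times the expected count. They were free_oligo:free_oligo at 10.8 (95% Poisson interval 10.2 to 11.5), free_oligo:Biotin at 6.75 (5.78 to 7.83) and CD28:CD28 at 2.59 (2.52 to 2.66). That of free_oligo:Biotin was 8.83 in rows A to D, 5.53 in rows E to H and 2.80 by the median over the 2 wells with an expected count of at least 1. For free_oligo:free_oligo, homotypic products left out of the margins gave 22.2. CD3:CD3 stood just below at 1.465 (1.428 to 1.502). It passed 1.5 in rows E to H (1.59, against 1.38 in rows A to D), by the median over wells (1.66), with margins of the summed counts (2.03) and with homotypic products left out of the margins (2.52). The latter pair of settings gave 3.99 and 5.81 for CD28:CD28. With homotypic products left out, random ligation alone gave 1.40 for CD3:CD3 and 1.56 for CD28:CD28. With margins of the summed counts it gave 1.39 and 1.54 on average. CD28:CD28 was above its expected count in 92 of 96 wells and CD3:CD3 in 96 of 96. The next products were PD1:ICAM1 at 1.23 (1.19 to 1.27), ICAM1:PD1 at 1.19, PD1:PDL1 at 1.17, PD1:CD3 at 1.14, CD3:PD1 at 1.13 and Biotin:PD1 at 1.09. Each of these 6 lay above its own range under random ligation, which was 0.970 to 1.03 for PD1:ICAM1. PD1:ICAM1 (0.994), ICAM1:PD1 (0.952), PD1:PDL1 (0.913) and Biotin:PD1 (0.939) were below 1 with homotypic products left out of the margins, where random ligation alone gave 0.970, 0.948, 0.927 and 0.974 on average. Of the 43 products, 15 lay above and 26 below their own ranges, and since products of a target share its totals, these are not independent of each other. At the low end, 5 products had at most 1/1.5 of the expected count, among them CD28:CD3 at 0.566 (0.535 to 0.597).

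In Raji, 1 of 39 products with at least 100 counts reached 1.5 times the expected count, again free_oligo:free_oligo, at 10.3 (9.27 to 11.5). ICAM1:B7 followed at 1.22 (1.17 to 1.26), ICAM1:free_oligo at 1.21, free_oligo:ICAM1 at 1.19 and Biotin:PDL1 at 1.14. ICAM1:Biotin and CD147:CD147 each had 1.10, CD147:PDL1 also had 1.10, B7:PDL1 had 1.09 and B7:ICAM1 1.06. Of the 39 products, 16 lay above and 17 below their own ranges under random ligation. Between 0.8 and 1.25 lay 30 of the 39 products, against 24 of 43 in Jurkat. Among products with at least 100 counts, a product of the background control was thus highest in both lines. Without the control products 1 product remained at or above 1.5 in Jurkat and 0 in Raji. Jurkat products under 100 counts with free_oligo in the second position rested on 21 to 73 counts each. They stood at 20.3 for HLADR, 18.4 for B7, 7.44 for PDL1, 6.26 for Biotin and 0.740 for ICAM1.

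**Figure D2:**
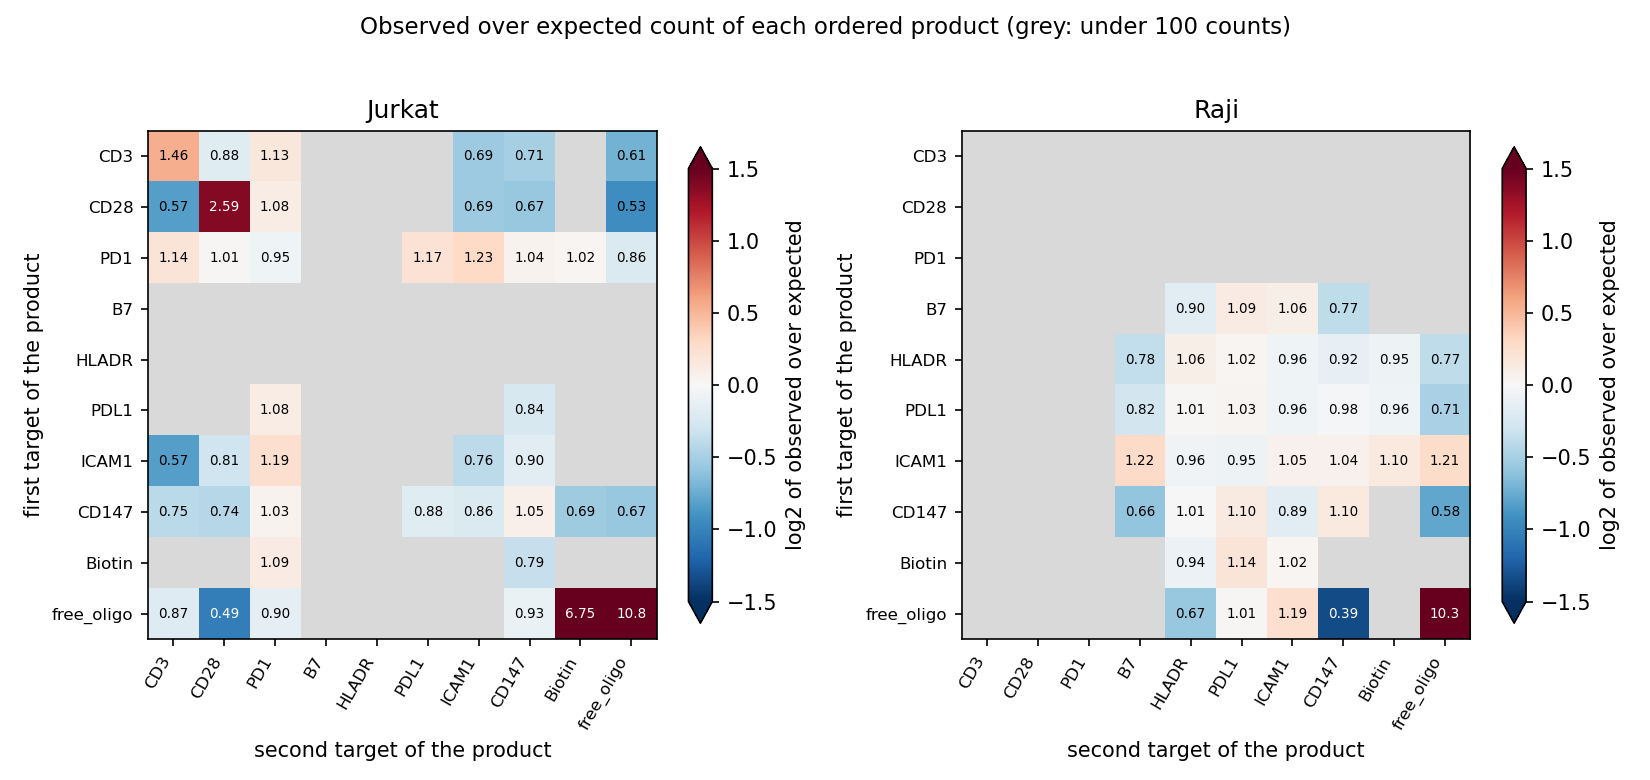
Observed over expected count under random ligation for each ordered product, Jurkat on the left and Raji on the right; rows give the first target, columns the second, colour the log2 value and grey a product under 100 counts. Values above 1.5 are few: free_oligo:free_oligo in both lines (10.8 and 10.3) and, in Jurkat, free_oligo:Biotin (6.75) and CD28:CD28 (2.59).

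Of the partner pairs listed beforehand, those with at least 100 counts showed no value at or above 1.5. The list also held HLADR with ICAM1 and CD147 with each protein, so it was not limited to pairs that bind each other. PD1 and its ligand PDL1 reached 100 counts in Jurkat alone. PD1:PDL1 had 350 counts at 1.17 times the expected count (1.05 to 1.30), and PDL1:PD1 had 443 at 1.08 (0.984 to 1.19). PDL1 lay below the background control in Jurkat (0.122% of probe ends against 1.11%), as did B7 in Raji (0.411% against 0.532%). Whether the products of these rare targets reflect bound protein was not tested. CD3:CD28 stood at 0.883 (0.845 to 0.921) in Jurkat. With margins of the summed counts it had 1.01, where random ligation alone gave 1.14 on average, so it stayed below random ligation. With homotypic products left out of the margins it had 1.35, where random ligation alone gave 1.16, so its direction turned there. CD28:CD3 stood at 0.566, and at 0.847 with homotypic products left out, where random ligation alone gave 1.12. CD28:PD1 had 1.08 and PD1:CD28 1.01, but 0.974 and 0.921 with margins of the summed counts, where random ligation alone gave 0.902 and 0.909. With homotypic products left out of the margins they had 1.015 and 0.935, where random ligation alone gave 0.950 and 0.955. PDL1 and B7 gave 1.09 for B7:PDL1 (1.04 to 1.15) and 0.823 for PDL1:B7 (0.765 to 0.884) in Raji. With margins of the summed counts B7:PDL1 had 0.943, where random ligation alone gave 0.860 on average, so it stayed above random ligation. PDL1 and B7 are partners on 1 cell if B7 is CD80, which the sources used here do not settle. HLADR and ICAM1 gave 0.960 and 0.965. CD147 with CD3 and with CD28 lay below expectation in both orders in Jurkat, between 0.672 and 0.754, while CD147:PD1 had 1.03 and PD1:CD147 1.04. The latter pair did not keep its direction in every setting, with 0.998 and 0.991 by margins of the summed counts and 1.004 and 0.998 with homotypic products left out. Random ligation alone gave 0.966 and 0.955, then 1.01 and 0.999. With homotypic products left out, CD28:CD147 had 1.01 and CD147:CD28 1.06, where random ligation alone gave 1.04 and 1.01 on average. CD28:CD147 was thus slightly below that average and CD147:CD28 above it. CD3:CD147 and CD147:CD3 had 0.889 and 0.919, where random ligation alone gave 0.954 and 0.934 on average. CD28 with B7 and HLADR with CD3 stayed under 100 counts in both lines.

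Homotypic products held 41.05% of Jurkat counts (40.93 to 41.17), against 40.6% expected under random ligation, and 35.9% of Raji counts (35.83 to 36), against 34.3%. In Raji, all 5 homotypic products with at least 100 counts had an interval above 1, with HLADR:HLADR at 1.06, ICAM1:ICAM1 at 1.05 and PDL1:PDL1 at 1.03. In Jurkat 4 of 6 did, with CD147:CD147 at 1.05, while PD1:PD1 had 0.953 (0.948 to 0.958) and ICAM1:ICAM1 0.761 (0.637 to 0.902). ICAM1:ICAM1 turned to 1.20 with margins of the summed counts and 1.25 with homotypic products left out of the margins, where random ligation alone gave 1.57 and 1.49. The homotypic products under 100 counts rest on few counts. In Raji, PD1:PD1 had 45 counts, of which 26 lay in well B01, at 254 times the expected count (185.5 to 340), CD28:CD28 had 5 at 218 (70.9 to 509) and CD3:CD3 had 0. In Jurkat, HLADR:HLADR had 14 counts at 186.3 (101.8 to 312.5), PDL1:PDL1 5 at 4.42 (1.43 to 10.3) and B7:B7 1 at 127.3 (3.22 to 709). Biotin:Biotin had 56 counts in Jurkat at 14.9 times the expected count (11.3 to 19.4) and 11 in Raji at 2.95 (1.47 to 5.29), and B7:B7 had 27 counts in Raji at 1.06 (0.699 to 1.54). This measure has a ceiling for abundant targets. In simulation, a PD1:PD1 product at 2 times random ligation gave 1.09. Random ligation alone gave 0.998 to 1.004 for PD1:PD1 in Jurkat, so the 0.953 seen lay below it. With homotypic products left out of the margins PD1:PD1 had 0.722 there, where random ligation alone gave 1.15 on average.

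The odds ratio of homotypic against mixed products, added after the data were seen, has no such ceiling. It was highest among the protein pairs for CD3 with CD28 in Jurkat, at 8.99 (8.87 to 9.29 with single wells left out in turn), where random ligation gave 0.891 to 1.13 over 100 draws. Pairs with the background control free_oligo gave 16.3 for PD1, 24.3 for CD147, 52.6 for CD3 and above 100 for CD28 in Jurkat, and from 7.54 for ICAM1 to 55.4 for CD147 in Raji. CD28 with CD147 gave 5.93, CD28 with ICAM1 3.73, CD3 with CD147 3.20, CD3 with ICAM1 3.07 and CD28 with PD1 2.46, each above its range under random ligation. CD3 with PD1 gave 1.07, against 0.964 to 1.04 under random ligation. PD1 with ICAM1 gave 0.483, below its range of 0.797 to 1.24, and PD1 with CD147 gave 0.930, below 0.986 to 1.02. ICAM1 with CD147 gave 1.06, within 0.777 to 1.25. In Raji, the pairs among HLADR, PDL1, ICAM1 and CD147 lay closely together, from 1.16 for HLADR with PDL1 (0.974 to 1.02 under random ligation) to 1.30 for PDL1 with ICAM1 (0.979 to 1.01). Taken from the summed counts, the odds ratio was 0.955 for PD1 with ICAM1, 1.12 for PD1 with CD147 and 2.11 for HLADR with PDL1. Random ligation alone then gave 1.56 to 2.335, 1.19 to 1.22 and 1.95 to 2.02, so these 3 pairs stayed on the same side of their ranges.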

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

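The alternatives without free_oligo and Biotin, without wells under 1000 counts (summed or as a mean over wells), without Raji wells A01 and B01 and with odds ratios of the summed counts were chosen after the results had been seen. The separation of wells by the T and B cell lists was kept, with 77 of 77 Jurkat and 0 of 95 Raji wells after thinning to 2411 counts, which left out 19 Jurkat wells. CD3 exceeded HLADR in 95 of 96 Jurkat wells, all but the well with 7 counts, and in 0 Raji wells. Of the alternative values for target share ratios, 51 stayed within the counting interval, 45 left it in the same direction and 1 reversed. This was Biotin, whose log2 ratio of Jurkat over Raji was -0.54 by mean count per well, since Raji wells were deeper. Of those for homotypic products, 56 stayed, 42 left the interval on the same side of 1, and 2 crossed 1. These were ICAM1:ICAM1 in Jurkat, at 1.20 with margins of the summed counts and 1.25 with homotypic products left out of the margins. Random ligation alone gave 1.49 under the latter setting, so it carries a bias of its own. For the named mixed products, 288 values stayed, 64 left the interval and 17 crossed 1 from an interval that left out 1. From an interval that included 1, 6 more crossed it. These were PD1:CD28 in Jurkat in rows E to H (0.997), with summed margins (0.921) and with homotypic products left out (0.935), PDL1:PD1 (0.8825) and CD147:PDL1 (1.13) in Jurkat under the latter, and CD147:HLADR in Raji in rows A to D (0.997). With margins of the summed counts the 17 included CD3:CD28 (1.01), CD28:PD1 (0.974), PD1:CD147 (0.991) and CD147:PD1 (0.998) in Jurkat and B7:PDL1 (0.943) in Raji. Random ligation alone then gave 1.14, 0.902, 0.955, 0.966 and 0.860 on average, so each stayed on the same side of random ligation. With homotypic products left out of the margins the rest were CD3:CD28 (1.35), CD28:CD147 (1.01), CD147:CD28 (1.06), PDL1:CD147 (1.09), ICAM1:CD147 (1.14), CD147:ICAM1 (1.06), PD1:PDL1 (0.913), PD1:ICAM1 (0.994), ICAM1:PD1 (0.952), PD1:CD147 (0.998) and Biotin:PD1 (0.939) in Jurkat and HLADR:ICAM1 (1.02) in Raji. With homotypic products left out, random ligation alone gave 1.04 for CD28:CD147, 0.970 for PD1:ICAM1 and 0.948 for ICAM1:PD1, so these kept their side. The others of this list turned against their averages, PD1:CD147 only narrowly. The odds ratio of PD1 with CD147 crossed 1 from the summed counts, at 1.12, where random ligation alone gave 1.19 to 1.22. By the median over wells with an expected count of at least 1, of which Jurkat had 26 and Raji only 3, free_oligo:free_oligo was 8.49 times expected in Jurkat and 6.91 in Raji. It was 13.6 and 11.7 in rows A to D and 8.80 and 8.65 in rows E to H.

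Products at least 2 times higher in Jurkat numbered 45 with no minimum share, and those in Raji 15 with a minimum share of 0.5%, as more and fewer products were then eligible. Products at least 1.5 times expected in Jurkat numbered 1 without the control, 1 without free_oligo and Biotin, 5 with homotypic products left out of the margins and 9 from at least 20 counts. In Raji they numbered 0, 0, 2 and 2 under these settings, and 0 from at least 1000 counts. With homotypic products left out, PDL1:PDL1 joined free_oligo:free_oligo in Raji at 1.77, where random ligation alone gave 1.72 on average. Shares with narrow counting intervals moved by a few points, and the cause was not tested. In rows A to D, rows E to H, without the control, without free_oligo and Biotin, and as a mean over wells, the T cell list in Jurkat held 63.7%, 60.5%, 63.1%, 63.3% and 59.1%. In that order the B cell list in Raji held 54.1%, 51.2%, 53.2%, 53.3% and 50.7%, and 52.9% without wells A01 and B01. Homotypic products held 41.6%, 40.3%, 41.7%, 41.9% and 39.4% in Jurkat, and 35.6%, 36.3%, 36.3%, 36.4% and 36.5% in Raji. No paired analysis was possible because no test was made, and a shared well name does not tie a Jurkat cell to a Raji cell. Depth limits the products under 100 counts. Of these, an observed over expected is given for homotypic ones, for Jurkat products with free_oligo in the second position and for some sums of products.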

Other observations

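All tests of explanations in this part were chosen after the results had been seen, and the limit of the depth test for free_oligo was lowered from 1.5 to 1 after its values were known.

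Wells of a line differed more in some targets than in others. Between the 10th and 90th percentile of wells, the PDL1 share in Raji spanned a factor of 17.1, against 3.12 for HLADR, 2.64 for ICAM1 and 2.65 for CD147. In Jurkat, the ICAM1 share spanned a factor of 15.7, CD3 10.9, CD28 7.29, CD147 1.83 and PD1 1.80. Numbers of probe ends, which also vary with the total of the well, spanned 9.41 for ICAM1, 20.8 for CD3, 13.3 for CD28, 6.82 for CD147 and 10.8 for PD1. The position of a target in a product also mattered. ICAM1 held 44.98% of first and 33.08% of second positions in Raji, and free_oligo held 1.479% and 0.737% in Jurkat but 0.407% and 0.657% in Raji.

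The PDL1 share of Raji cells had an SD of 16.7 percentage points over 95 wells. It was under 5% in 15 wells, in the first and the second position alike, and 50% or more in 10 wells. A split of wells into 2 sets by total held a small part of this spread, but such a split cannot measure the whole link to the total. The total also includes the counts of PDL1 products. Among the 15 wells under 5%, all but B03 (15316 counts) and E08 (13276) lay below the median total of 12549. The 47 shallower wells averaged 20.4% and the 48 deeper wells 30.98%, but the difference held 10.1% of the variance, and the SDs within these sets were 17.3 and 14.4. The 8 plate rows held 16.5% of the variance, where chance gives 7.45%, with row means from 18.2% to 36.5%, which argues against the row as the whole account, and the rest stays open, since staining and capture per well were not measured and no biological explanation was tested.

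Raji wells held 67 counts of products that join 2 T cell list targets. Random ligation of the few T cell probe ends in each well would give 0.343 counts, a ratio of 195 (151.3 to 248), whereas products of a T cell target with a B cell list target or ICAM1 stood at 0.864 (0.803 to 0.928). Wells A01 and B01 held 39 of the 67, and the other wells still had a ratio of 194 (128.8 to 280.2). Carry-over as the whole source, at the ratio of the summed Jurkat wells, is argued against for the summed counts of A01 and B01. Their 34 counts of PD1:PD1 would bring about 46.7 counts of PD1 with CD147 (at least 32.3), and 5 were seen (1.62 to 11.7). Single Jurkat wells differed in these targets, with 72.7% PD1 and 18.4% CD147 in E06, for example. Carry-over from single Jurkat wells, or as a part of the source, was not tested. Of these 34 counts, 26 lay in B01 and 8 in A01. Neither well was tested on its own, so carry-over into A01 alone stays open. In the other wells carry-over cannot be told apart from random ligation for PD1 with CD147, since 17 counts were seen (9.90 to 27.2), where the Jurkat ratio needs 15.1 and random ligation gives 21.7, and Jurkat wells likewise held 24 counts of products of 2 B cell list targets, 12.5 times the expected count (7.998 to 18.57).

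The free_oligo:free_oligo product stood at 10.8 and 10.3 times its expected count in Jurkat and Raji (10.2 to 11.5 and 9.27 to 11.5). A few wells did not hold most of its counts, as the 5 fullest wells held 22.1% in Jurkat (19.6 to 24.8) and 16.2% in Raji (12.5 to 20.6). This does not show an even spread over wells, which was not tested. In Jurkat its mean count per well was 0.927 times as high in the 48 deeper as in the 48 shallower wells (0.818 to 1.05), although totals differed 3.24 times, which is consistent with an amount per well that does not depend on the total of the well. In Raji the ratio was 1.72 (1.38 to 2.16) with totals that differed 2.15 times, which argues against a fixed amount per well as the whole account there. The intervals cover counting error only, and what free_oligo is stays open in the sources used here.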
